A study of Mus musculus with 96 samples.

How the data were processed

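RNA was measured in interscapular brown adipose tissue (iBAT) and inguinal white adipose tissue (iWAT) of male C57BL/6J mice. The labels gave 12 groups of 8 libraries, 96 in all: each tissue from wild-type and Ucp1-KO mice on control diet at 20 °C, control diet at 30 °C and high fat diet at 30 °C. The labels give no sequencing batch. The labels number the libraries from 1 to 96 and give no number that ties an iBAT library to an iWAT library of the same animal.

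The libraries were built with a stranded mRNA kit per the labels. The authors deposited a single table of transcript abundances in RPKM (reads per kilobase of transcript and per mega (M) reads), with 168326 transcripts and a column for each library. The submitters' processing notes name CASAVA and bcl2fastq. The aligner, the counting tool and the genome build are not given in the sources used here, so no coordinates are printed. The neighbours of Ucp1 were taken from a reference gene table of the mouse, which may differ from the build the authors used.

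The number of reads behind each library was recovered from the spacing of its low RPKM values: 94.9 to 95.7% of the values of up to 20 reads were whole reads within 0.05 of a read. This gave 8.91 to 19.2 M reads per library, with a median of 11.85 M. A single read on a transcript of 1 kb then stood for 0.052 to 0.112 RPKM. The highest correlation between libraries of the same tissue was r = 0.990, over log2 values of transcripts, and no libraries held identical values.

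Transcripts were reduced to genes by symbol. Of the symbols with several transcripts above 0, 17.0% had transcripts with identical values in all 96 libraries, so reads appear to have been counted for more than 1 transcript; the transcript with the highest mean over all libraries therefore stood for its gene. Transcripts without an Entrez gene identifier (13.8% of transcripts, 9.85% of the summed RPKM) were left out, which left 29072 symbols. Genes with at least 0.5 RPKM in at least 8 libraries of a fit were tested: 14807 in iBAT, 15897 in iWAT and 16310 in the fit of both tissues.

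Values were analysed as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (limma-trend, empirical Bayes with an intensity trend). The file holds RPKM, so the tests planned for read counts were replaced by the test planned for normalized values. Each tissue was fitted with its 6 group means over its 48 libraries, and tissues were compared in a fit of all 96 libraries with 12 group means. Differences were taken as 20 °C minus 30 °C on control diet, Ucp1-KO minus wild-type within each condition, high fat minus control diet at 30 °C, and iBAT minus iWAT. Differences between these effects were tested as interaction contrasts. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The test was checked on simulated data: with 200 genes changed in values modelled on wild-type iBAT at the 2 temperatures, 62.7%, 89.6% and 95.5% of genes changed 1.5, 2 and 4-fold were recovered, and 3.5% of calls were false. For iWAT the shares recovered were 59.7%, 85.1% and 93.9%, with 4.2% false calls. In the simulations genes varied independently with the fitted spread, and the composition of the libraries did not shift. The shares of false calls are therefore not those of the real comparisons.

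The comparisons, the main test, the rule for named genes and 24 gene lists were fixed before the data were examined. The lists were brown thermogenic genes, lipogenesis, fatty acid oxidation, nuclear genes of oxidative phosphorylation, genes of the mitochondrial genome, glucose uptake and glycolysis, lipid uptake and lipolysis, creatine and calcium cycling, the integrated stress response, the unfolded protein response, the interferon response, cholesterol synthesis, white depot and adipocyte genes, extracellular matrix, macrophage, T cell, B cell, endothelial, Schwann and nerve, skeletal muscle, epithelial, erythroid, proliferation and circadian clock genes. Ucp1 was left out of the thermogenic list in comparisons of genotype. Lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 423 list tests of the 18 comparisons within tissues. Camera asks whether a list moved apart from all other genes. Of these tests 208 passed, and 28 passed with a correlation estimated from the data. With limma's fry, which asks whether the genes of a list moved on balance 1 way, 196 passed.

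Genes named in the text followed a rule. Ucp1 was reported in every group. In each comparison the 8 largest rises and 8 largest falls were eligible among genes past the threshold with a mean of at least 5 RPKM in the higher group, or in interactions the 6 genes with the smallest p each way. The 4 members of each list with the smallest p could be named too, as could Ucp1, Fgf21, Gdf15, Dio2, Elovl3, Cidea, Ppargc1a, Lep, Adipoq, Fasn and Acly in any comparison. Unnamed and predicted genes were skipped.

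Alternatives fixed in advance were quantile normalization, array weights, no filter on low values, a stricter filter of 1 RPKM, a fit of only the groups compared, the sum of transcripts per gene and a pseudocount of 0.1. Chosen after seeing the data were the RefSeq mRNA row with the highest mean for each gene, a median-ratio scaling of the RPKM, the skeletal muscle and B cell list means as covariates, and a fit without 15 libraries. Those were 14 libraries with a mean log2(RPKM + 1) of 6 or more over the skeletal muscle list and 1 iWAT library with a mean below 2 over the B cell list; this definition was itself settled after the values were seen. Every comparison was also repeated with 100 splits of its libraries, the real split included. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.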

Results

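Gene expression was measured in interscapular brown adipose tissue (iBAT), the main heat-producing fat depot of the mouse, and in inguinal white adipose tissue (iWAT), a subcutaneous depot. The mice were male C57BL/6J animals, wild-type or Ucp1-KO. Ucp1 encodes uncoupling protein 1, the mitochondrial proton carrier through which brown fat makes heat. Mice of each genotype spent 4 weeks on a control diet (13% of energy from fat) at 20 °C, on the control diet at 30 °C, or on a high fat diet (48% of energy from fat) at 30 °C, which is thermoneutral for the mouse. Each of the 12 groups of tissue, genotype and condition held 8 libraries. The libraries of a group came from separate animals per the series design, and no label ties an iBAT library to the iWAT library of the same animal. Depth ran from 8.91 to 19.2 M reads per library, with group means between 10.5 M in wild-type iBAT on high fat diet and 13.49 M in Ucp1-KO iBAT on control diet at 30 °C. The study asked how temperature, diet and the loss of Ucp1 shape the transcriptomes of brown and white fat.

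Changes are given as differences of log2(RPKM + 1) with their SE from limma, 8 libraries per group, and adjusted p-values are from limma. On this scale the changes of genes near or below 1 RPKM are understated. RPKM are shares of a library, so each comparison is given with the median change of all genes, and with the share of calls that were higher under 2 other scalings where these moved it by more than 10 points.

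Ucp1 RNA was the first value read in every group. In wild-type iBAT, Ucp1 had a mean of 3793 ± 751 RPKM (SD, n = 8) at 20 °C, 8227 ± 577 at 30 °C and 6466 ± 902 on high fat diet. In Ucp1-KO iBAT the means were 1005 ± 91.7, 736 ± 168 and 778 ± 147 RPKM, so reads of the gene were still counted in every library labelled Ucp1-KO. In iWAT the wild-type means of Ucp1 were 133 ± 96.7 RPKM at 20 °C, 33.4 ± 41.2 at 30 °C and 15.3 ± 11.6 on high fat diet. Libraries of iWAT labelled Ucp1-KO had 306 ± 128, 83.9 ± 32.1 and 12.9 ± 7.93 RPKM of Ucp1. The labels do not say which part of the gene the allele lacks, and in iWAT the level of Ucp1 therefore does not check the genotype. Mri1, a gene on the same chromosome that was chosen after its values were seen, was at most 6.52 RPKM in the 24 iWAT libraries labelled Ucp1-KO and at least 7.56 RPKM in the 24 wild-type libraries. In iBAT the ranges of Mri1 overlapped, 1.49 to 5.05 RPKM in Ucp1-KO and 1.97 to 5.09 RPKM in wild-type libraries.

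**Figure D1:**
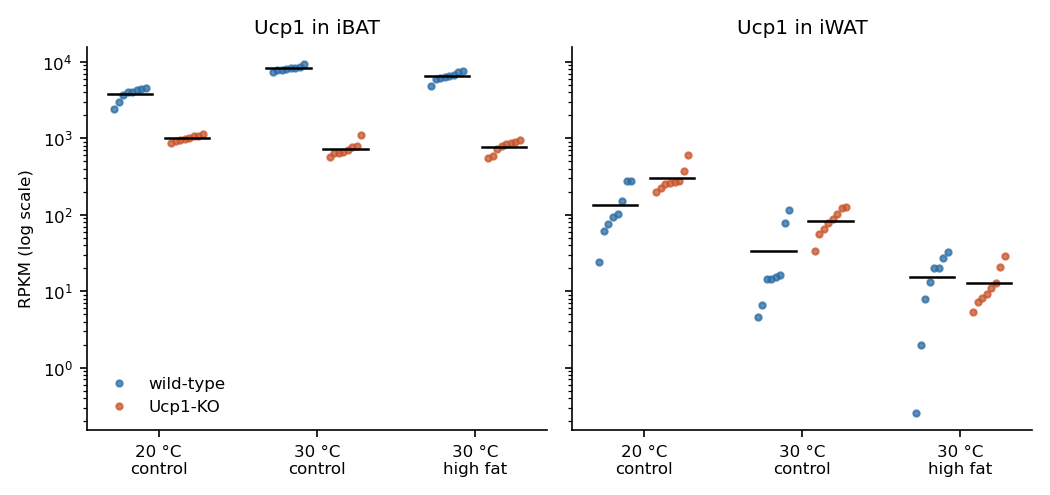
RPKM of Ucp1 (log scale) in iBAT and iWAT for the 3 conditions, with a point per library and a black bar at the mean of each group of 8. Wild-type iBAT had 3793 RPKM at 20 °C and 8227 RPKM at 30 °C, and in iWAT the means labelled Ucp1-KO lay above the wild-type means on control diet at both temperatures.

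In wild-type iBAT, RNA of the enzymes that build fatty acids and sterols was higher at 20 °C than at 30 °C. Fasn, the fatty acid synthase, rose by 3.01 ± 0.30 and Acly, which supplies cytosolic acetyl-CoA, by 2.96 ± 0.27. Scd2, Acaca and Fdft1 rose by 1.63 to 2.43. Of 20 lipogenesis genes 16 rose and 1 fell, and of 18 cholesterol synthesis genes 14 rose and 2 fell (17, 1, 14 and 2 adjusted over the list alone). Ucp1 changed by −1.14 ± 0.12 (adjusted p = 3.1e-10) and Ppargc1a, a coactivator of mitochondrial genes, by −2.26 ± 0.24 (adjusted p = 1.8e-10, limma), both lower at 20 °C. Dio2, the deiodinase that activates thyroid hormone, changed by −0.59 ± 0.19, a call lost with median-ratio scaling (−0.43), while Elovl3, an elongase of very long chain fatty acids, rose by 0.88 ± 0.29. Of 30 thermogenic genes 7 rose and 10 fell, the same numbers as adjusted over the list alone.

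Stress, matrix and macrophage genes were lower at 20 °C in the same wild-type iBAT. The integrated stress response, the program that raises amino acid and folate enzymes under stress, fell in 15 of 23 genes and rose in 1. Gdf15, a stress cytokine, changed by −2.25 ± 0.35, Mthfd2 by −1.92 ± 0.21, Pck2 by −1.03 ± 0.11 and Fgf21, a metabolic hormone, by −0.59 ± 0.22. The unfolded protein response fell in 13 of 17 genes and rose in 1, and extracellular matrix fell in 21 of 22, with Col4a1 at −1.46 ± 0.11. These counts were the same adjusted over the list alone. Macrophage markers fell in 15 of 20 genes (17 adjusted over the list alone), among them Mpeg1 at −1.57 ± 0.27. Interferon genes fell in 9 of 22 (the same adjusted over the list alone) and T cell markers in 4 of 13 (3 adjusted over the list alone), and no B cell marker passed. Endothelial markers fell in 9 of 12 and rose in 1 (the same adjusted over the list alone), with Cldn5 at −1.81 ± 0.19. Ptgds, a prostaglandin D synthase, changed by −4.37 ± 0.31, Hmox1, heme oxygenase 1, by −3.31 ± 0.22 and Nnat by −2.53 ± 0.35. Among 17 clock genes 7 rose, including Dbp (1.44 ± 0.21) and Per3 (1.52 ± 0.15), and 4 fell, including Arntl (−1.78 ± 0.14), the same adjusted over the list alone.

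In that comparison 6610 of 14807 genes differed, 1723 higher and 4887 lower at 20 °C, with a median change of −0.12 over all genes. The share of calls that were higher was 26.1%, against 50.5% with median-ratio scaling and 49.7% with quantile normalization. Relative to all genes, camera called lipogenesis (list median 1.27, adjusted p = 5.7e-17) and cholesterol synthesis (0.95, adjusted p = 6.0e-16) up, and with an estimated correlation their adjusted p was 0.0347 and 0.0125. Extracellular matrix (−0.81) was called down at adjusted p = 1.2e-05, and adjusted p = 0.535 with an estimated correlation. The integrated stress response had adjusted p = 0.0169, and adjusted p = 0.644 with an estimated correlation. No skeletal muscle marker passed the test.

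Ucp1-KO iBAT at 20 °C carried more RNA for heat production, fat oxidation and respiration than at 30 °C. Fatty acid oxidation genes rose in 19 of 22 (Hadha 1.01 ± 0.07, Acadl 1.07 ± 0.07), nuclear genes of oxidative phosphorylation in 36 of 43 (Uqcrc1, a complex III subunit, 1.00 ± 0.09), and all 7 measured genes of the mitochondrial genome rose. Of 30 thermogenic genes 19 rose and 4 fell, and all these numbers were the same adjusted over the list alone. Ppargc1a rose by 0.93 ± 0.24, Elovl3 by 1.97 ± 0.29, Fabp3, a fatty acid carrier, by 1.87 ± 0.25 and Ucp1 by 0.47 ± 0.12 (adjusted p = 0.00073, limma). Among large rises were Scd3 (4.53 ± 0.25), a stearoyl-CoA desaturase, Ptgds (4.27 ± 0.31), Cyp2b10 (4.10 ± 0.32) and Acot11, an acyl-CoA thioesterase (3.26 ± 0.28), and Fgf21 rose by 2.63 ± 0.22. Lipogenesis rose in 16 of 20 genes, glucose uptake and glycolysis in 14 of 22 and cholesterol synthesis in 13 of 18, while 2, 3 and 3 fell (all the same adjusted over the list alone).

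Immune and matrix genes of Ucp1-KO iBAT were lower at 20 °C than at 30 °C. All 22 interferon response genes fell, among them Cxcl10, an interferon-induced chemokine (−2.92 ± 0.28), as did all 22 extracellular matrix genes (Mmp14 −2.41 ± 0.17), all 20 macrophage markers (Trem2 −3.34 ± 0.28, Mpeg1 −3.05 ± 0.27), all 13 T cell markers and all 9 Schwann and nerve markers, each the same adjusted over the list alone. Ubd, a ubiquitin-like protein induced by interferon, changed by −4.28 ± 0.28, Hmox1 by −3.79 ± 0.22 and Apoe by −3.35 ± 0.17. White depot and adipocyte genes fell in 11 of 14 and rose in 1, and proliferation genes fell in 15 of 16 (the same adjusted over the list alone), of which 4 and 11 were lower with quantile normalization and median-ratio scaling. The lists of fatty acid oxidation (adjusted p = 2.5e-20) and cholesterol synthesis (adjusted p = 1.3e-08) were called up by camera, with adjusted p = 0.0433 and 0.0452 with an estimated correlation. Thermogenic genes had adjusted p = 6.1e-11, and adjusted p = 0.0855 with an estimated correlation. The interferon list had adjusted p = 3.6e-05, and adjusted p = 0.651 with an estimated correlation. In all, 10866 genes differed, 2058 higher and 8808 lower, with a median change of −0.34. Higher calls made up 18.9%, against 45.9% with median-ratio scaling and 53.2% with quantile normalization.

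The temperature response of iBAT differed between the genotypes in the interaction test. Ucp1, Ppargc1a and Ptgds, which were lower at 20 °C in wild-type and higher in Ucp1-KO iBAT, had interaction values of 1.61 ± 0.18, 3.19 ± 0.34 and 8.64 ± 0.43 (adjusted p = 5.2e-10, 3.1e-10 and 3.7e-20, limma). Fgf21 (3.22 ± 0.32), Gdf15 (1.83 ± 0.50), Fabp3 (3.03 ± 0.35) and Acot2, a mitochondrial acyl-CoA thioesterase (3.32 ± 0.24), also had positive interactions, and Vim, an intermediate filament of mesenchymal cells (−2.95 ± 0.17) and Trem2 (−2.80 ± 0.40) negative ones. Gdf15 did not rise in Ucp1-KO iBAT (−0.42 ± 0.35, adjusted p = 0.276, limma), and its interaction rests on the fall in wild-type iBAT (−2.25 ± 0.35). Interactions were positive in 19 of 29 thermogenic genes and negative in 1 (20 and 1 adjusted over the list alone), and positive in 15 of 22 fatty acid oxidation genes (18 adjusted over the list alone). They were positive in 17 of 43 nuclear oxidative phosphorylation genes, and positive in 13 and negative in 3 of 23 integrated stress genes, the same adjusted over the list alone. They were negative in 21 of 22 interferon genes (22 adjusted over the list alone) and 17 of 20 macrophage markers (19 adjusted over the list alone). For the thermogenic list camera gave adjusted p = 5.3e-12, and adjusted p = 0.0629 with an estimated correlation. In all, 7762 genes had an interaction, 1761 positive and 6001 negative, with a median of −0.24. The positive ones made up 22.7%, against 45.4% with median-ratio scaling and 52.6% with quantile normalization.

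At 20 °C, Ucp1-KO iBAT had higher RNA of stress hormones and of the integrated stress response than wild-type iBAT. Gdf15 was higher by 4.83 ± 0.35 and Fgf21 by 4.69 ± 0.22 (adjusted p = 1.4e-15 and 2.3e-21, limma), and the serine and folate enzyme gene Mthfd2, the pseudokinase gene Trib3 and the transcription factor gene Atf5 by 3.46 ± 0.21, 3.03 ± 0.19 and 1.98 ± 0.13. Of 23 integrated stress genes 19 were higher and 1 lower (21 and 1 adjusted over the list alone), a call that held in camera with the preset (adjusted p = 1.7e-17) and an estimated correlation (adjusted p = 0.0163). Unfolded protein response genes were higher in 11 of 17, the same adjusted over the list alone, with Hspa5, the main chaperone of the endoplasmic reticulum, at 0.57 ± 0.06. Interferon genes were higher in 21 of 22 (21 higher and 1 lower adjusted over the list alone), with Cxcl10 at 2.13 ± 0.28 and Irf7 at 1.97 ± 0.26. Camera gave adjusted p = 2.5e-07, and adjusted p = 0.545 with an estimated correlation.

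In the same comparison of genotypes at 20 °C, Ucp1 differed by −1.89 ± 0.12 (adjusted p = 4.3e-17, limma), while Ppargc1a (2.27 ± 0.24), Elovl3 (1.87 ± 0.29), Acot2 (2.96 ± 0.17), Ehhadh, an enzyme of peroxisomal fat oxidation (1.70 ± 0.14), Hk1, a hexokinase (2.36 ± 0.17), and Plin2, a lipid droplet coat protein (1.80 ± 0.14), were higher in Ucp1-KO iBAT. Lipogenesis genes were lower in 9 of 20 and higher in 2 (10 and 2 adjusted over the list alone), with Fasn at −0.98 ± 0.30 and Dgat2, which makes triglyceride, at −1.47 ± 0.18. By camera the list had adjusted p = 0.0161, and adjusted p = 0.678 with an estimated correlation. All 7 genes of the mitochondrial genome were lower, the same adjusted over the list alone, with COX1 at −0.82 ± 0.16 (at the same change not called with no filter on low values). Of 43 nuclear oxidative phosphorylation genes 1 was higher and 3 were lower (0 and 1 adjusted over the list alone). Lipid uptake and lipolysis genes were higher in 8 of 20 and lower in 2, and creatine and calcium cycling genes were higher in 5 of 12, both the same adjusted over the list alone. Macrophage markers were higher in 12 of 20 and lower in 2 (13 and 2 adjusted over the list alone), with Gpnmb, a glycoprotein of macrophages, at 3.03 ± 0.37. All 5 erythroid markers were higher, the same adjusted over the list alone. In all, 5601 genes differed, 3661 higher and 1940 lower, with a median of 0.06. Genes higher in Ucp1-KO made up 65.4% of calls, against 50.2% with median-ratio scaling and 45.2% with quantile normalization.

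**Figure D2:**
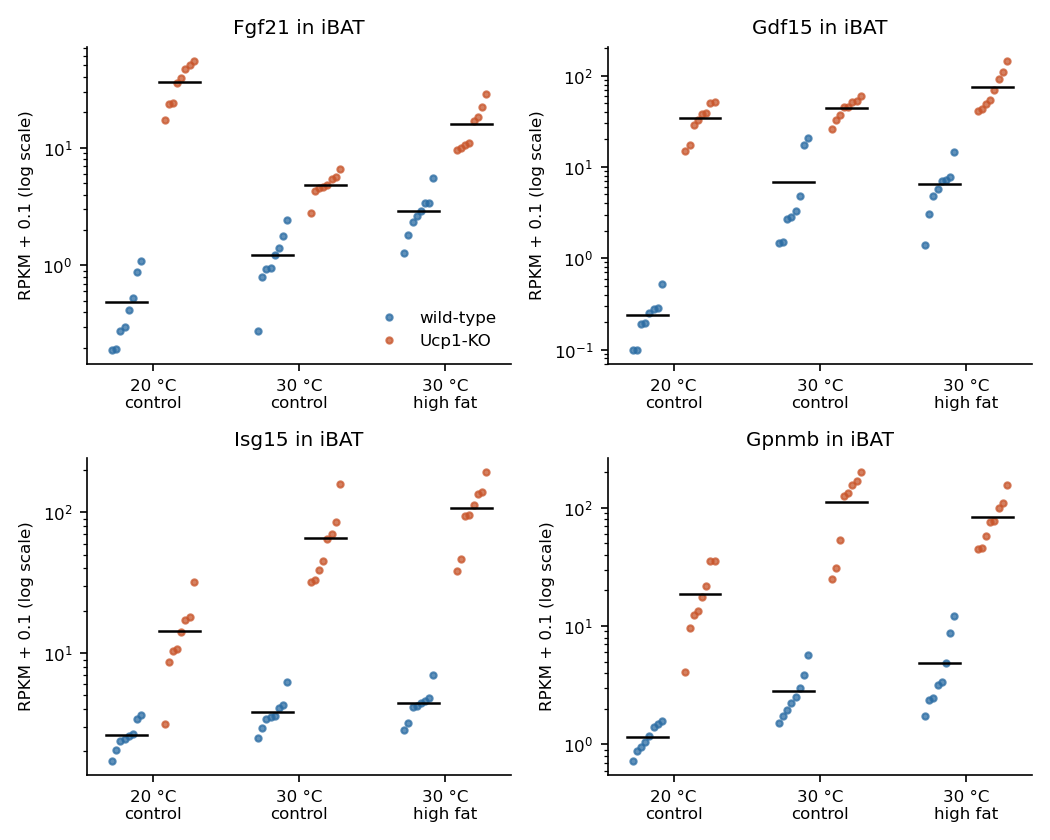
RPKM + 0.1 (log scale) of Fgf21, Gdf15, Isg15 and Gpnmb in iBAT, with a point per library and a black bar at the mean of each group of 8. At 20 °C every Ucp1-KO library lay above every wild-type library for Fgf21, Gdf15 and Gpnmb.

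At 30 °C on control diet, the iBAT of Ucp1-KO mice carried more RNA of interferon, macrophage and matrix genes and less of mitochondrial genes than wild-type iBAT. All 22 interferon genes were higher, among them Cxcl10 (3.74 ± 0.28), Isg15 (3.66 ± 0.30) and Irf7 (3.59 ± 0.26), and Ubd was higher by 3.85 ± 0.28. Macrophage genes were higher in 18 of 20 and lower in 1 (19 and 1 adjusted over the list alone), with Gpnmb at 4.67 ± 0.37, Lgals3, a lectin, at 4.22 ± 0.27, Ctss, a lysosomal protease, at 3.63 ± 0.32 and Trem2 at 3.61 ± 0.28. All 22 extracellular matrix genes (Mmp14 2.08 ± 0.17, Timp1 1.86 ± 0.24), all 13 T cell markers (Lck 1.27 ± 0.18) and all 9 Schwann and nerve markers were higher, the same adjusted over the list alone. Proliferation genes were higher in 14 of 16 (15 adjusted over the list alone), of which 5 passed with quantile normalization. Gdf15 was higher by 3.01 ± 0.35 and Fgf21 by 1.47 ± 0.22, and integrated stress genes were higher in 16 of 23 and lower in 1, with Slc7a11, a cystine transporter, at 1.88 ± 0.16 and Atf3 at 2.70 ± 0.26. Unfolded protein response genes were higher in 14 of 17, and both lists gave the same counts adjusted over the list alone.

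Ucp1 differed by −3.51 ± 0.12 at 30 °C (adjusted p = 1.2e-26, limma) and Ptgds by −4.21 ± 0.31. All 7 genes of the mitochondrial genome were lower (COX1 −1.45 ± 0.16), as were 29 of 43 nuclear oxidative phosphorylation genes (Ndufv1, a complex I subunit, −0.93 ± 0.10), the same adjusted over the list alone. Fatty acid oxidation genes were lower in 16 of 22 and higher in 1 (17 and 1 adjusted over the list alone), with Crat at −0.58 ± 0.07. Thermogenic genes were lower in 17 of 29 and higher in 4, the same adjusted over the list alone, with Otop1, a proton channel, at −1.10 ± 0.11 and Pank1, which starts coenzyme A synthesis, at −1.24 ± 0.12. The mitochondrial genome list was called by camera at adjusted p = 2.7e-08, and adjusted p = 0.0493 with an estimated correlation. The interferon list had adjusted p = 3.1e-12, and adjusted p = 0.314 with an estimated correlation. For macrophages adjusted p = 6.5e-05 became adjusted p = 0.611 with an estimated correlation. In all, 9583 genes differed, 8025 higher and 1558 lower, with a median of 0.27. Calls higher in Ucp1-KO were 83.7%, against 52.7% with median-ratio scaling and 42.0% with quantile normalization. The medians of the lists for lipogenesis, cholesterol synthesis, lipid uptake and lipolysis, and the clock were above 0 here and below 0 with median-ratio scaling.

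On high fat diet at 30 °C, Ucp1-KO iBAT had more RNA of interferon, matrix and immune genes and less of mitochondrial genes than wild-type iBAT. Interferon genes were higher in 22 of 22 (Cxcl10 4.72 ± 0.28, Ifit3 4.41 ± 0.31, Isg15 4.22 ± 0.30), extracellular matrix genes in 21 of 22 (Col1a2 1.80 ± 0.20), T cell markers in 13 of 13 (Lck 1.80 ± 0.18) and unfolded protein response genes in 16 of 17 (Hspa5 0.85 ± 0.06), the same adjusted over the list alone. Macrophage markers were higher in 18 of 20 and lower in 1 (19 and 1 adjusted over the list alone), B cell markers in 6 of 7 (7 adjusted over the list alone), and Ighm, the heavy chain of IgM, by 4.85 ± 0.55. Integrated stress genes were higher in 18 of 23 and lower in 1, the same adjusted over the list alone, with Gdf15 at 3.43 ± 0.35, Fgf21 at 2.11 ± 0.22 and the serine synthesis gene Psat1 at 2.37 ± 0.18. Ucp1 differed by −3.07 ± 0.12 (adjusted p = 4.0e-24, limma), Cidea, a lipid droplet protein of brown fat, by −0.89 ± 0.14 and Cyp2b10 by −3.39 ± 0.32. Nuclear oxidative phosphorylation genes were lower in 36 of 43, all 7 genes of the mitochondrial genome were lower (ND5 −1.46 ± 0.15), and thermogenic genes were lower in 17 of 29 and higher in 3, all the same adjusted over the list alone. All 5 erythroid markers were lower, the same adjusted over the list alone, but without the 15 libraries rich in muscle or poor in B cell RNA 1 of 5 was. Endothelial markers were lower in 4 of 12 and higher in 1, the same adjusted over the list alone.

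Muscle RNA moved with this comparison: 11 of 20 skeletal muscle markers were higher in Ucp1-KO iBAT on high fat diet, the same adjusted over the list alone, with Tnnt3 at 2.56 ± 1.05 (adjusted p = 0.0313, limma). With quantile normalization 3 of them passed and with median-ratio scaling 1. The call of Tnnt3 was lost with median-ratio scaling (2.29) and, at 2.56, with only the groups compared. It was also lost without the 15 libraries (1.10) and with the muscle and B cell means as covariates (0.29). Of the libraries left out there, those in this comparison were sample numbers 43, 47 and 48, all Ucp1-KO. Lep, the gene of leptin, was higher by 0.88 ± 0.36, and was not called without those 15 libraries (0.68), with quantile normalization (0.56), median-ratio scaling (0.59), array weights (0.67), the muscle and B cell means as covariates (0.16) or only the groups compared (0.88). The mitochondrial genome list had adjusted p = 1.3e-08, and adjusted p = 0.0452 with an estimated correlation, and oxidative phosphorylation adjusted p = 4.9e-24, and adjusted p = 0.206 with an estimated correlation. In all, 9458 genes differed, 7823 higher and 1635 lower, with a median of 0.25. The share higher in Ucp1-KO was 82.7%, against 51.1% with median-ratio scaling and 41.1% with quantile normalization.

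High fat diet at 30 °C raised endothelial genes and lowered lipid synthesis genes in wild-type iBAT. All 12 endothelial markers rose, the same adjusted over the list alone, with Pecam1 at 0.67 ± 0.10 and Kdr, a receptor of vascular growth factor, at 0.66 ± 0.10. The camera test gave adjusted p = 7.1e-08, and adjusted p = 0.174 with an estimated correlation. Lipogenesis genes fell in 12 of 20 and rose in 1 (14 and 1 adjusted over the list alone), with Fasn at −0.99 ± 0.30, Scd1 at −1.31 ± 0.20 and Slc25a1, the citrate carrier, at −1.28 ± 0.19. Glucose uptake and glycolysis genes fell in 11 of 22 and rose in 4 (12 and 4 adjusted over the list alone). Ptgds changed by −3.70 ± 0.31, Elovl3 by −2.21 ± 0.29, Acsl5 by −1.87 ± 0.16 and Klb, the co-receptor of FGF21, by −1.97 ± 0.18 (adjusted p = 1.5e-11, limma). Lep rose by 1.71 ± 0.36, Sncg by 1.69 ± 0.23, the early response genes Fos and Egr1 by 1.93 ± 0.39 and 1.43 ± 0.33, and Adrb3, the adipocyte adrenoceptor, by 1.13 ± 0.19. All 5 erythroid markers rose, the same adjusted over the list alone, and 4 of 5 without the 15 libraries. In all, 4890 genes differed, 2739 higher and 2151 lower, with a median of 0.02.

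In Ucp1-KO iBAT, high fat diet raised Ighm, Igj, the unfolded protein response and Fgf21, and lowered lipogenesis. Ighm rose by 2.75 ± 0.55 and Igj, the antibody joining chain, by 2.77 ± 0.41 (adjusted p = 0.00032 and 3.3e-06, limma), Lep by 2.17 ± 0.36, Sncg by 2.53 ± 0.23, Mest, an imprinted gene, by 1.13 ± 0.14 and Fgf21 by 1.48 ± 0.22. None of 7 B cell markers passed (2 rose adjusted over the list alone). The unfolded protein response rose in 10 of 17 genes, the same adjusted over the list alone, with Pdia4 at 0.62 ± 0.12 and Dnajb9 at 0.48 ± 0.09. For this list camera gave adjusted p = 7.2e-08, and adjusted p = 0.0855 with an estimated correlation. Integrated stress genes rose in 10 of 23 and fell in 1 (12 and 2 adjusted over the list alone), with Trib3 at 0.86 ± 0.19. Lipogenesis fell in 10 of 20 genes (12 adjusted over the list alone), Elovl6 at −1.15 ± 0.15 and Fasn at −0.96 ± 0.30 (not called without the 15 libraries, at −0.95, or, at the same change, with only the groups compared) among them, and Cidea changed by −0.97 ± 0.14. The acute phase genes Orm2 and Itih4 changed by −2.03 ± 0.22 and −1.96 ± 0.26. In all, 2424 genes differed, 1237 higher and 1187 lower, with a median of −0.01. Without the 15 libraries named above the number was 1298. In the interaction test, the diet response of iBAT differed between genotypes for 970 genes, 411 positive and 559 negative with a median of −0.03. Endothelial markers had negative values in 4 of 12 (11 adjusted over the list alone), with Pecam1 at −0.55 ± 0.14. Pgf, a placental growth factor, had an interaction of −1.76 ± 0.27, and Ptgds of 2.85 ± 0.43 (adjusted p = 6.8e-05, limma; 2.08 and not called with a pseudocount of 0.1). Without the 15 libraries the number of interactions was 550.

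**Figure D3:**
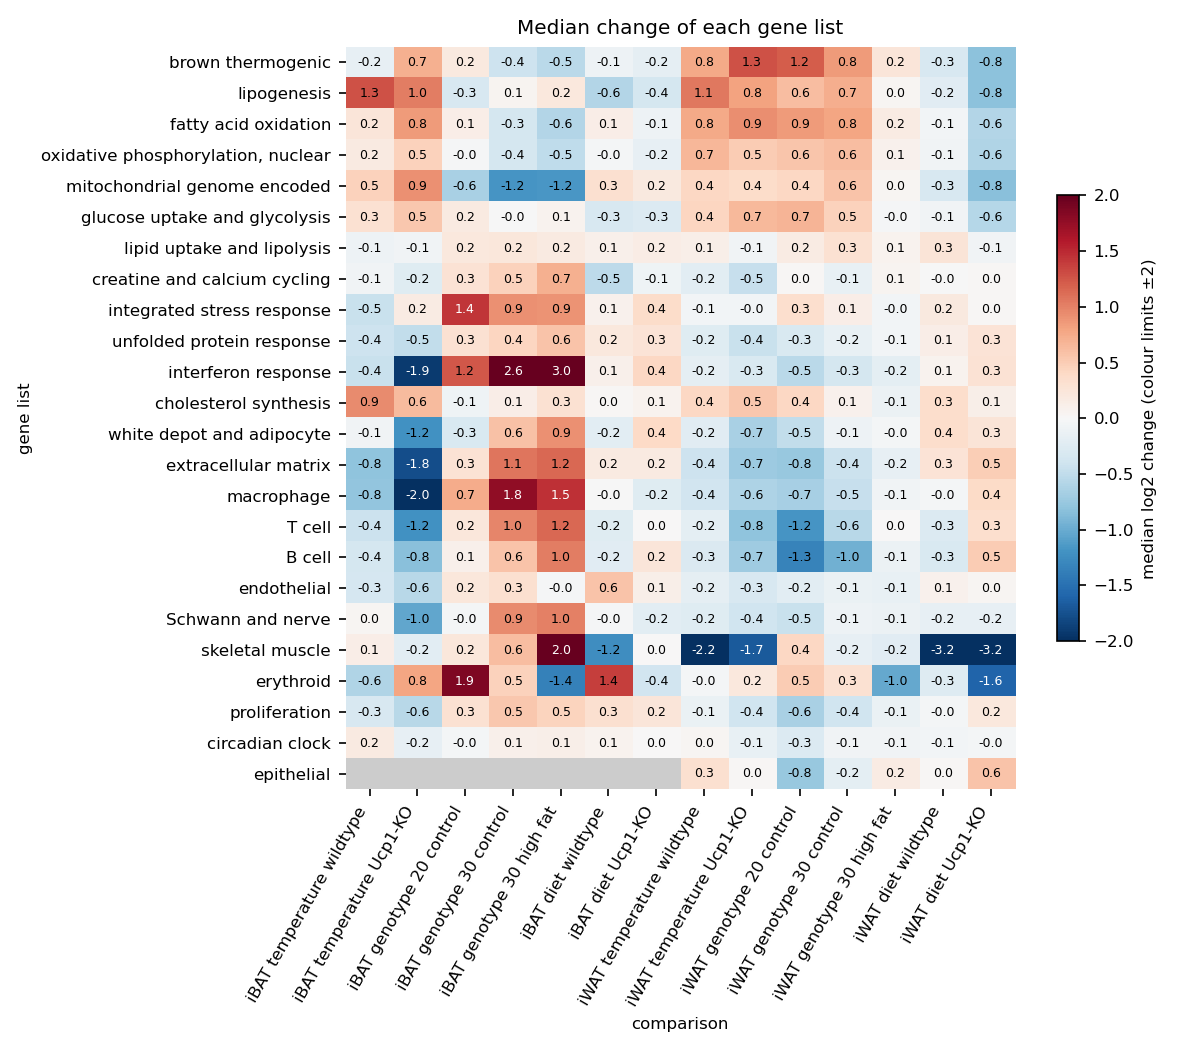
Median log2 change of 24 gene lists in the 14 comparisons of temperature, genotype and diet within tissues, with the tissue, the factor and the fixed level named below each column (color limits −2 and 2; grey, not tested). The values that changed sign with quantile normalization or median-ratio scaling all lay between −0.31 and 0.31.

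In wild-type iWAT, genes of heat production, lipogenesis and respiration were higher at 20 °C than at 30 °C. Ucp1 rose by 2.37 ± 0.54 (adjusted p = 0.0018, limma), Cidea by 2.14 ± 0.28, Elovl3 by 2.28 ± 0.35, Otop1 by 2.14 ± 0.21, Cox8b, a cytochrome oxidase subunit of brown fat and muscle, by 1.79 ± 0.22 and Dio2 by 1.09 ± 0.32, the last at 0.97 and not called without the 15 libraries. Thermogenic genes rose in 19 of 29 (19 higher and 1 lower adjusted over the list alone), fatty acid oxidation genes in 20 of 22 (20 higher and 1 lower adjusted over the list alone; Hadha 0.93 ± 0.10, Acaa2 1.12 ± 0.13), and nuclear oxidative phosphorylation genes in 42 of 43 (the same adjusted over the list alone; Ndufv1 0.83 ± 0.10). Lipogenesis rose in 14 of 20 genes (16 adjusted over the list alone), with Elovl6 at 2.70 ± 0.30, Fasn at 2.54 ± 0.30 and Acly at 2.37 ± 0.26. Cholesterol synthesis rose in 12 of 18 (13 adjusted over the list alone), with Nsdhl at 1.18 ± 0.15 and Insig1 at 1.11 ± 0.19. With an estimated correlation these 5 lists kept their camera calls, with adjusted p = 0.0313, 0.0255, 0.0347, 0.0174 and 0.0347 in that order. Glucose uptake and glycolysis rose in 12 of 22 genes and fell in 1 (15 and 1 adjusted over the list alone), Eno1 by 1.17 ± 0.13.

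Extracellular matrix genes fell in 7 of 22 at 20 °C in wild-type iWAT (9 adjusted over the list alone), with Col4a1 at −0.63 ± 0.14, and Nnat changed by −1.80 ± 0.35. No T cell, B cell or macrophage marker passed the test. None of the 17 skeletal muscle markers passed, with a list median of −2.17. Trim63 and Tpm2, genes of muscle fibers outside the list, changed by −2.20 ± 0.76 and −1.78 ± 0.64 (adjusted p = 0.0363 and 0.0438, limma). Both calls were lost at the same changes with no filter and with only the groups compared, and with median-ratio scaling at −2.14 and −1.69. That of Trim63 was also lost with a pseudocount of 0.1, at −3.01. Without the 15 libraries Trim63 and Tpm2 were at −0.70 and −0.57 and not called, and with the covariates at −0.65 and −0.52 and not called. Camera gave the muscle list adjusted p = 0.0266, and adjusted p = 0.784 with an estimated correlation. In all, 3116 of 15897 genes differed, 1152 higher and 1964 lower, with a median of −0.10. Genes higher at 20 °C were 37.0% of calls, against 69.6% with median-ratio scaling and 64.7% with quantile normalization.

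In iWAT labelled Ucp1-KO, genes of heat production, fat oxidation and lipid synthesis were also higher at 20 °C than at 30 °C. Fabp3 rose by 3.69 ± 0.36, Acot11 by 3.68 ± 0.26, Elovl3 by 3.37 ± 0.35, Phospho1 by 2.76 ± 0.21, Dio2 by 2.27 ± 0.32, Ucp1 by 1.88 ± 0.54 (adjusted p = 0.0032, limma) and Ppargc1a by 1.28 ± 0.13. The hormones Fgf21 and Gdf15 rose by 1.84 ± 0.23 and 0.95 ± 0.22. Thermogenic genes rose in 23 of 29 and fell in 1 (23 and 2 adjusted over the list alone), fatty acid oxidation genes in 20 of 22 and fell in 1 (the same adjusted over the list alone; Acot2 1.93 ± 0.13), and glucose uptake and glycolysis genes in 17 of 22 and fell in 1 (18 and 1 adjusted over the list alone; Pfkl 1.49 ± 0.12). With an estimated correlation camera gave these 3 lists adjusted p = 0.0128, 0.0296 and 0.023. Nuclear oxidative phosphorylation genes rose in 37 of 43 (39 adjusted over the list alone), and the camera call at adjusted p = 3.6e-37 had adjusted p = 0.0855 with an estimated correlation. Lipogenesis rose in 15 of 20 genes and fell in 1 (the same adjusted over the list alone), and cholesterol synthesis rose in 12 of 18 and fell in 3 (13 and 3 adjusted over the list alone). Camera gave lipogenesis adjusted p = 1.4e-14, and adjusted p = 0.0585 with an estimated correlation, and kept cholesterol synthesis (adjusted p = 0.0383).

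White adipocyte genes fell in 11 of 16 and rose in 1 (12 and 1 adjusted over the list alone) at 20 °C in iWAT labelled Ucp1-KO, with Adipoq, the gene of adiponectin, at −0.92 ± 0.13, Lep at −1.29 ± 0.41 (−0.96 and not called with median-ratio scaling) and Cfd, adipsin, at −1.42 ± 0.25. Schwann and nerve markers fell in 10 of 11, the same adjusted over the list alone, and extracellular matrix genes fell in 19 of 22, the same adjusted over the list alone. Markers of T cells fell in 11 of 14 (12 adjusted over the list alone), macrophages in 13 of 20 and endothelium in 9 of 12 (the last 2 the same adjusted over the list alone). With quantile normalization 0, 6 and 2 of these passed and with median-ratio scaling 0, 1 and 0, where the endothelial median turned from −0.31 to 0.01. B cell markers fell in 6 of 12 (3 adjusted over the list alone) and in 0 with either scaling, and skeletal muscle markers in 4 of 17 (the same adjusted over the list alone; Myh1 −1.78 ± 0.58). In all, 9598 genes differed, 1434 higher and 8164 lower, with a median of −0.25. The share higher at 20 °C was 14.9%, against 61.4% with median-ratio scaling and 53.6% with quantile normalization. In the interaction test 2110 genes differed between genotypes in their temperature response, 342 positive and 1768 negative with a median of −0.16 (16.2% positive, 83.4% with median-ratio scaling and 72.5% with quantile normalization). Among them were Scd3 (2.37 ± 0.23), Acot2 (1.55 ± 0.19), Fabp3 (2.61 ± 0.51), Ppargc1a (1.19 ± 0.18; adjusted p = 2.6e-05, limma), Fgf21 (1.36 ± 0.32, at 1.61 and not called with a pseudocount of 0.1) and Cfd (−1.27 ± 0.35, not called with quantile normalization, at −0.59, or, at the same change, with no filter). The thermogenic list was positive in 5 of 28 genes (7 adjusted over the list alone).

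Comparing genotypes at 20 °C, iWAT labelled Ucp1-KO had higher RNA of brown fat genes than wild-type iWAT. Elovl3 was higher by 4.07 ± 0.35, Dio2 by 3.38 ± 0.32, Fabp3 by 3.08 ± 0.36, Phospho1 by 2.79 ± 0.21, Gyk, glycerol kinase, by 2.78 ± 0.24, Cidea by 1.96 ± 0.28, Ppargc1a by 1.54 ± 0.13 and Ucp1 by 1.48 ± 0.54 (adjusted p = 0.0165, limma). Fgf21 and Gdf15 were higher by 1.77 ± 0.23 and 1.68 ± 0.22. Sample number 64 of the Ucp1-KO group lay apart from its group in Ucp1, Fgf21, Gdf15 and Elovl3, and no fit of this comparison left it out. Thermogenic genes were higher in 23 of 28 and lower in 1, fatty acid oxidation genes in 21 of 22 and lower in 1 (Acot2 2.35 ± 0.13, Hadha 1.33 ± 0.10), and glucose uptake and glycolysis genes in 18 of 22 and lower in 1 (Pdk4 1.89 ± 0.22), all the same adjusted over the list alone. Their camera values with an estimated correlation were adjusted p = 0.0125, 0.0347 and 0.0246. Nuclear oxidative phosphorylation genes were higher in 39 of 43 (40 adjusted over the list alone), and camera's adjusted p = 2.8e-34 became adjusted p = 0.101 with an estimated correlation.

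Lymphocyte genes were lower in the same iWAT libraries labelled Ucp1-KO at 20 °C: 12 of 12 B cell markers (Pax5 −1.43 ± 0.28) and 14 of 14 T cell markers (Cd3g −1.44 ± 0.31; adjusted p = 0.00011, limma). Proliferation genes were lower in 17 of 17 (Mki67 −1.03 ± 0.20), and white adipocyte genes in 11 of 16 and higher in 1, all 4 lists the same adjusted over the list alone. Camera called B cell markers at adjusted p = 0.0474, and adjusted p = 0.816 with an estimated correlation. With the muscle and B cell means as covariates, Cd3g (−0.32) and Mki67 (−0.31) were not called. The B and T cell means of iWAT libraries went together within groups (r = 0.958). Whether these markers came from the fat itself or from other tissue taken along with it was not tested. Macrophage markers were lower in 16 of 20 (17 adjusted over the list alone), in 9 of 20 with quantile normalization. Interferon genes were lower in 13 of 22 and higher in 1 (the same adjusted over the list alone), of which 6 and 4 were lower with quantile normalization and median-ratio scaling, while Cxcl10 was higher by 1.53 ± 0.35. Epithelial markers were lower in 6 of 7 (7 adjusted over the list alone), in 2 with quantile normalization. Endothelial markers were lower in 6 of 12, the same adjusted over the list alone, in 0 with either scaling, which turned their median from −0.21 to 0.05 and 0.11. In all, 10305 genes differed, 1566 higher and 8739 lower, with a median of −0.27. Of these calls 15.2% were higher, against 52.6% with median-ratio scaling and 50.8% with quantile normalization.

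At 30 °C on control diet, iWAT labelled Ucp1-KO again had more RNA of brown fat, lipogenic and respiratory genes. Elovl3 was higher by 2.98 ± 0.35, Cidea by 2.28 ± 0.28, Dio2 by 2.20 ± 0.32, Gyk by 2.03 ± 0.24, Otop1 by 1.73 ± 0.21, Elovl6 by 2.01 ± 0.30 and Fasn by 1.56 ± 0.30. Ucp1 was higher by 1.97 ± 0.54 (adjusted p = 0.0098, limma), and by 1.63 and not called without the 15 libraries. Thermogenic genes were higher in 20 of 28 (21 adjusted over the list alone), lipogenesis genes in 14 of 20 (16 adjusted over the list alone), fatty acid oxidation genes in 21 of 22 and lower in 1, and nuclear oxidative phosphorylation genes in 42 of 43 (Uqcrq 0.92 ± 0.12), the last 2 the same adjusted over the list alone. Camera kept these 4 calls with an estimated correlation (adjusted p = 0.0128, 0.0383, 0.0255 and 0.0347). Lipid uptake and lipolysis genes were higher in 7 of 20, the same adjusted over the list alone, with Plin5, a lipid droplet protein of oxidative tissue, at 1.69 ± 0.19.

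B cell markers were lower in 12 of 12 in that comparison, the same adjusted over the list alone, with Ighm at −1.27 ± 0.35, Faim3 at −1.22 ± 0.40 and Cr2, a complement receptor, at −0.97 ± 0.28. Macrophage markers were lower in 8 of 20 (11 adjusted over the list alone), and the macrophage genes Marco and Timd4 changed by −1.32 ± 0.37 and −1.31 ± 0.35 (adjusted p = 0.0080 for Timd4, limma). Marco and Timd4 were at −0.87 and −0.93 and not called without the 15 libraries, 5 of which were in this comparison, and at −0.32 and −0.42 and not called with the muscle and B cell covariates. Ighm, Faim3 and Cr2 were at −1.05, −0.74 and −0.72 and not called without those 15 libraries. With the covariates, which rest in part on B cell genes, they were at −0.48, −0.04 and −0.17 and not called. Sample number 79, among the libraries left out, had a B cell mean of 1.65 in this Ucp1-KO group, whose mean was 4.30. Faim3 was also not called, at the same change, with only the groups compared. Camera called B cell markers down at adjusted p = 0.0014, and adjusted p = 0.666 with an estimated correlation. In all, 3781 genes differed, 1199 higher and 2582 lower, with a median of −0.12. Of the calls 31.7% were higher, against 66.0% with median-ratio scaling and 65.2% with quantile normalization. Without the 15 libraries 1001 genes differed, 625 higher and 376 lower.

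On high fat diet the genotypes differed in iWAT in 45 genes, 31 higher and 14 lower in libraries labelled Ucp1-KO, with a median of −0.04 (68.9% higher, 84.4% with median-ratio scaling and 88.7% with quantile normalization). Fitting only the groups compared called 13 genes, while array weights called 2630, of which 942 were higher and 1688 lower. Ucp1 differed by 0.18 ± 0.54 (adjusted p = 0.99), Elovl3 by 0.78 ± 0.35 (adjusted p = 0.491) and Cidea by 0.99 ± 0.28 (adjusted p = 0.137, limma); none passed. Hmgcs1, an early enzyme of cholesterol synthesis, was higher by 1.00 ± 0.14, Plin5 by 0.87 ± 0.19, Clstn3 by 0.85 ± 0.17, Rasd1 by 1.32 ± 0.29 and Krt79, a keratin, by 0.97 ± 0.17. Plin5, Clstn3 and Rasd1 lost their calls at the same changes when only the groups compared were fitted. Scoc, a neighbour of Ucp1 on its chromosome, was lower by the largest amount (−1.20 ± 0.11, adjusted p = 8.3e-10, limma), and Mri1 and Ptger1, from the same region, changed by −0.70 ± 0.08 and −0.55 ± 0.11. Ptger1 was not called with only the groups compared, at the same change, or with the sum of its transcripts (−0.29). Of the thermogenic list 1 of 28 genes was higher (4 adjusted over the list alone), with camera at adjusted p = 3.2e-12, and adjusted p = 0.0654 with an estimated correlation.

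High fat diet at 30 °C raised Mest, Sfrp5, Npr3 and Lep in wild-type iWAT. Mest rose by 3.12 ± 0.45, Sfrp5, a secreted Wnt inhibitor, by 2.67 ± 0.38, Npr3, the natriuretic peptide clearance receptor, by 2.27 ± 0.37, Lep by 2.11 ± 0.41 and Angptl4, an inhibitor of lipoprotein lipase, by 0.83 ± 0.16 (adjusted p = 0.00025, limma). White adipocyte genes rose in 6 of 16 and fell in 3 (7 and 3 adjusted over the list alone), cholesterol synthesis genes rose in 6 of 18 (7 adjusted over the list alone) and extracellular matrix genes in 8 of 22 (11 adjusted over the list alone), with Thbs1 the largest at 1.59 ± 0.28. Thermogenic genes fell in 8 of 29 and rose in 1 (13 and 2 adjusted over the list alone), with Cidea at −1.62 ± 0.28 and Elovl3 at −1.23 ± 0.35 (−1.15 and not called with the covariates). Lipogenesis fell in 8 of 20 and rose in 1 (the same adjusted over the list alone), with Fasn at −1.07 ± 0.30 (at the same change not called with only the groups compared). Camera gave the thermogenic list adjusted p = 9.7e-06, and adjusted p = 0.349 with an estimated correlation.

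Skeletal muscle markers fell in 11 of 17 on high fat diet in wild-type iWAT (12 adjusted over the list alone), with Ckm, muscle creatine kinase, at −4.02 ± 1.34, Tnnt3 at −3.96 ± 1.26 and Atp2a1, the calcium pump of fast muscle, at −3.82 ± 1.21 (adjusted p = 0.0369, 0.0272 and 0.0265, limma). Camera gave the muscle list adjusted p = 6.6e-08, and adjusted p = 0.385 with an estimated correlation. Ckm lost its call with no filter, at −4.02, and with a pseudocount of 0.1, at −4.33. Without the 15 libraries Ckm, Tnnt3 and Atp2a1 were at −2.19, −2.23 and −2.21, and none of them was called. In all, 2150 genes differed, 1540 higher and 610 lower, with a median of 0.00 (71.6% higher, 60.6% with median-ratio scaling). Without the 15 libraries 1025 genes differed.

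**Figure D4:**
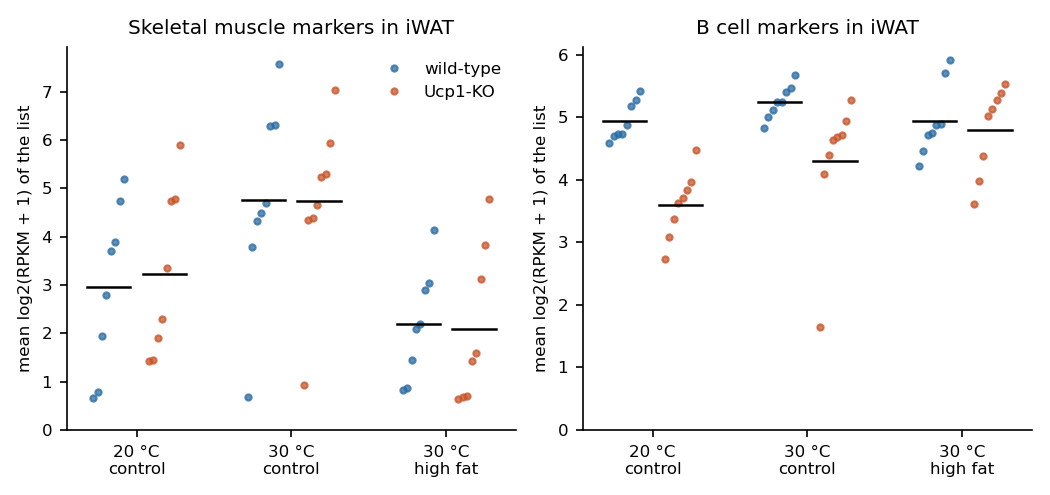
Mean log2(RPKM + 1) of the 17 measured skeletal muscle markers and the 12 measured B cell markers in iWAT, with a point per library and a black bar at the mean of each group of 8. Muscle means ran from 0.69 to 7.58 among wild-type libraries on control diet at 30 °C, and a single library labelled Ucp1-KO had a B cell mean of 1.65.

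In iWAT labelled Ucp1-KO, high fat diet lowered thermogenic, lipogenic and mitochondrial genes. Elovl3 changed by −3.43 ± 0.35, Elovl6 by −3.41 ± 0.30, Cidea by −2.91 ± 0.28, Fasn by −2.81 ± 0.30, Ucp1 by −2.68 ± 0.54 (adjusted p = 0.00024, limma) and Dio2 by −2.21 ± 0.32. Thermogenic genes fell in 20 of 29 and rose in 2 (22 and 3 adjusted over the list alone), lipogenesis genes fell in 14 of 20 and rose in 1 (16 and 1 adjusted over the list alone), nuclear oxidative phosphorylation genes fell in 42 of 43 (Uqcrq −0.98 ± 0.12) and all 7 genes of the mitochondrial genome fell, the last 2 the same adjusted over the list alone. With an estimated correlation these 4 camera calls had adjusted p = 0.0174, 0.0347, 0.0493 and 0.0424. Glucose uptake and glycolysis genes fell in 14 of 22 and rose in 1 (14 and 2 adjusted over the list alone), with Pdha1, a subunit of pyruvate dehydrogenase, at −1.26 ± 0.12.

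Mest rose by 3.72 ± 0.45 in the same comparison, Sfrp5 by 2.43 ± 0.38, Lep by 2.23 ± 0.41 and Npr3 by 2.05 ± 0.37. Extracellular matrix genes rose in 11 of 22 (Col6a3 0.94 ± 0.17), macrophage markers in 4 of 20 (Cd68 0.72 ± 0.24 and Gpnmb 0.86 ± 0.29, at 0.62 and 0.80 and not called without the 15 libraries, nor with the covariates, at 0.50 and 0.75, nor Gpnmb, at the same change, with only the groups compared), and unfolded protein response genes in 11 of 17 with 1 lower, each the same adjusted over the list alone. Skeletal muscle markers fell in 11 of 17 (14 adjusted over the list alone), with Ckm at −4.33 ± 1.34 and Myh4 at −3.89 ± 1.26 (adjusted p = 0.0152 and 0.0204, limma), which were not called with array weights (−3.31 and −2.80). Without the 15 libraries Ckm and Myh4 were at −3.505 and −2.973 and not called either. Camera gave the list adjusted p = 2.0e-08, and adjusted p = 0.349 with an estimated correlation. In all, 3873 genes differed, 2552 higher and 1321 lower, with a median of 0.09 (65.9% higher, 44.2% with either scaling).

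The diet response of iWAT differed between genotypes for 212 genes in the interaction test, 16 positive and 196 negative, with a median of 0.08. Array weights called 4706 genes and turned the balance, with 3035 positive and 1671 negative. Nuclear oxidative phosphorylation genes had negative interactions in 22 of 43 (41 adjusted over the list alone), with Uqcrq at −1.04 ± 0.17 (adjusted p = 0.0018, limma). Fatty acid oxidation genes were negative in 7 of 22 (18 negative and 1 positive adjusted over the list alone), with Acaa2 at −1.07 ± 0.18, and thermogenic genes in 5 of 28 (16 adjusted over the list alone), with Otop1 at −1.32 ± 0.29 and Pank1 at −1.12 ± 0.23. Elovl3, Elovl6 and Fasn had interactions of −2.20 ± 0.50, −2.23 ± 0.42 and −1.74 ± 0.42, while that of Ucp1 was −1.79 ± 0.77 and did not pass (adjusted p = 0.247). For oxidative phosphorylation camera gave adjusted p = 2.2e-46, and adjusted p = 0.0548 with an estimated correlation. Without the 15 libraries 47 genes had an interaction, and Elovl3, Fasn and Otop1 were at −2.06, −1.76 and −1.16 and not called. Elovl3 was also not called with the sum of transcripts (−2.14) or a pseudocount of 0.1 (−1.90), nor Fasn with the covariates (−1.47).

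Between tissues, iBAT carried more RNA of thermogenic and nuclear oxidative phosphorylation genes than iWAT in each of the 6 groups of mice. The 7 genes of the mitochondrial genome were all higher in iBAT in each wild-type group, while in Ucp1-KO mice none differed at 20 °C, 2 were lower in iBAT at 30 °C and 5 were higher on high fat diet, the same adjusted over the list alone. In wild-type mice Ucp1 was higher in iBAT by 5.16 ± 0.40 at 20 °C, 8.67 ± 0.40 at 30 °C and 9.21 ± 0.40 on high fat diet (adjusted p = 4.9e-21, 5.1e-35 and 8.5e-37, limma). At 20 °C Dio2, Fabp3 and Cox7a1 were higher by 4.79 ± 0.26, 4.52 ± 0.31 and 4.08 ± 0.25, Gyk was higher by 5.75 ± 0.20 at 30 °C, and Cpt1b, which admits fatty acids to mitochondria, by 6.37 ± 0.20 on high fat diet. Thermogenic genes were higher in iBAT in 27 of 30 at 20 °C and 28 of 30 at 30 °C in wild-type mice, and nuclear oxidative phosphorylation genes in 43 and 42 of 43, the same adjusted over the list alone. Lymphocyte markers were higher in iWAT: 12 of 12 B cell and 14 of 14 T cell markers in every group, the same adjusted over the list alone, with Ighm, Cd79b and the macrophage receptor Marco at −6.25 ± 0.47, −5.93 ± 0.32 and −5.60 ± 0.28 in wild-type mice at 20 °C. Skeletal muscle markers were higher in iBAT in 10, 8 and 5 of 20 in wild-type mice at 20 °C, at 30 °C and on high fat diet (10, 7 and 2 adjusted over the list alone), and in 9, 7 and 19 of 20 in Ucp1-KO mice (9, 7 and 20 adjusted over the list alone).

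Wild-type iBAT and iWAT differed in 13082 of 16310 genes at 20 °C (2584 higher and 10498 lower in iBAT, median −0.43), 13263 at 30 °C (3188 and 10075, median −0.43) and 12823 on high fat diet (2724 and 10099, median −0.41). Higher shares of 19.8%, 24.0% and 21.2% became 45.6%, 44.1% and 45.0% with median-ratio scaling and 56.9%, 53.8% and 54.2% with quantile normalization. In Ucp1-KO mice 10254 genes differed at 20 °C (3294 and 6960, median −0.15), 10142 at 30 °C (4296 and 5846, median −0.07) and 11331 on high fat diet (3996 and 7335, median −0.16). At 20 °C and on high fat diet the shares of 32.1% and 35.3% became 47.8% and 44.8% with median-ratio scaling and 55.3% and 49.7% with quantile normalization. Ptgds (4.57 ± 0.27) and Gmpr (4.99 ± 0.26) were higher in Ucp1-KO iBAT at 20 °C, where Ucp1 differed by 1.79 ± 0.40. Interferon genes were lower in iBAT in 21 of 22 in each wild-type group and higher in iBAT in 21 of 22 at 30 °C and 22 of 22 on high fat diet in Ucp1-KO mice, where at 20 °C 3 were higher and 8 lower in iBAT, the same adjusted over the list alone.

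The response to temperature also differed between tissues in the interaction test. In wild-type mice 2738 genes differed (827 positive and 1911 negative, median −0.03; 30.2% positive, 43.4% and 44.4% with median-ratio scaling and quantile normalization), with Ucp1 at −3.51 ± 0.57, Ppargc1a at −2.35 ± 0.28, Gdf15 at −2.12 ± 0.42 and Ptgds at −4.42 ± 0.39 (adjusted p = 1.5e-06, 2.2e-10, 8.2e-05 and 1.6e-15, limma). Thermogenic genes were negative in 19 of 30 (20 adjusted over the list alone). In Ucp1-KO mice 4160 genes differed (1093 positive and 3067 negative, median −0.07; 26.3% positive, 52.9% and 51.6% with the 2 scalings), with Srxn1 and Sqstm1, which respond to oxidative stress, at −3.20 ± 0.23 and −2.08 ± 0.19, Fosl1 at −3.08 ± 0.28 and Cpne5 at 3.16 ± 0.18. Interferon genes were negative in 22 of 22 and macrophage markers in 16 of 20, the same adjusted over the list alone. Ppargc1a had an interaction of −0.35 ± 0.28 that did not pass (adjusted p = 0.39).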

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

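Chosen after the results were seen were the tests of exchanged labels, of library composition gene by gene, of the transcript standing for Ucp1, of muscle in the dissections, of a uniform fall, of the genes beside Ucp1, and all repeats with other splits of the libraries. In 84 groups of 8 values, 13 values from 8 samples lay far from the other 7 of their group, by a gap above Dixon's critical value for the whole range. For normally spread values chance alone sets a sample apart in about 1 in 20 groups. RPKM were taken without a log and several groups held the same samples, so the 13 cannot be set against that share.

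In brown fat, sample number 4 (wild-type, 20 °C) had 0.42 RPKM of the stress cytokine gene Gdf15, a high value in a group near 0. Sample number 30 (Ucp1-KO, 30 °C on control diet) had the most reads of its group, 19.22 M, with high Ucp1 (1112 RPKM) and high Elovl3 (542.5 RPKM). Sample number 37 (wild-type, high fat) stood apart in Elovl3, at 175.9 RPKM. In iWAT, sample number 54 (wild-type, 20 °C) had 2.62 RPKM of the hormone gene Fgf21. Sample number 64 (labelled Ucp1-KO, 20 °C) was apart in 4 genes: Ucp1 at 597.4, Fgf21 at 15.4, Gdf15 at 10.0 and Elovl3 at 741.4 RPKM. Sample number 75 (labelled Ucp1-KO, 30 °C on control diet) had a skeletal muscle mean of 0.934, and sample number 79 of the same group a B cell mean of 1.65. Sample number 87 (wild-type, high fat) had 5.57 RPKM of Elovl3.

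Genes passed the threshold in all 6 interaction tests. For genotype with diet in iWAT 2 of 100 splits of the libraries gave as many genes, and chance stays open there. The response to temperature differed between genotypes for 7762 genes in iBAT and 2110 in iWAT, and the response to diet for 970 in iBAT and 212 in iWAT. Between tissues the response to temperature differed for 2738 genes in wild-type and 4160 in Ucp1-KO mice.

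Ucp1 and Ppargc1a, both genes of heat production, were lower at 20 °C than at 30 °C in wild-type iBAT. Exchanged labels of these 2 groups would turn their temperature changes against those of Ucp1-KO iBAT, but across genes the changes went together (r = 0.484), and lipogenesis was higher at 20 °C in both genotypes. The choice of the transcript was argued against too, since the change nearest 0 of the 2 genes with another choice was −1.13. Composition (RPKM are shares) was argued against as the whole cause for Ppargc1a, at −2.085 with quantile normalization, and could not be told apart for Ucp1, which stayed lower past the threshold at −0.974 with median-ratio scaling and at −0.424 with quantile normalization, which fixes the top ranks. A true response to 4 weeks at 20 °C and the animals of the 2 groups stay open and were not tested.

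Skeletal muscle genes were lower on high fat diet in iWAT of both genotypes. The 17 measured muscle genes moved together among libraries of the same group, with a mean pairwise r of 0.679 over 48 libraries, which is what muscle in part of the dissections would give. A uniform fall in every high fat library could not be told apart from this: 14 of the 16 lay above the lowest control library at 30 °C, but only 3 did without sample numbers 65 and 75. Muscle carried along in some dissections may explain the pattern, as a hypothesis found in the same data. Whether diet changed how cleanly the depot could be taken was not tested.

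Genes beside Ucp1 on its chromosome differed between genotypes in both tissues, among them Scoc and Usp38. In iWAT on high fat diet 6 of the 200 nearest tested genes were called (3.0%), against 35 of 14687 elsewhere (0.238%). Alleles carried along with the Ucp1 locus could not be told apart from other causes. Without the 4 genes seen before the test, Scoc, Usp38, Mri1 and Ptger1, 2 of 196 were called (1-sided Fisher exact p = 0.0851). Leaving out 4 of the 6 called genes left this test little to find, so it speaks neither for nor against linked alleles. For Scoc and Usp38, normalization, filter or row choice was argued against, since 0 of 132 values under the alternatives lost the call or reversed. An effect of lost Ucp1 on its neighbours stays open and was not tested.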

How the results depend on the processing

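Chosen after the results were seen were median-ratio scaling, the RefSeq mRNA row, the muscle and B cell covariates and the fit without 15 libraries, while the other settings were planned. No paired analysis was possible because no label ties the iBAT and iWAT libraries of an animal. Alternatives planned for read counts were not run because the file holds RPKM. Of 289 counts under the alternatives, 286 of genes and 3 of list tests, 260 stayed within 1.5 times the main count. For the 29 others the cause was not tested.

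Quantile normalization gave 5813 genes for temperature in iWAT labelled Ucp1-KO, 71 for genotype in iWAT on high fat diet, and in iWAT 870 interactions of genotype with temperature and 346 with diet. Median-ratio scaling gave 6118 for temperature in iWAT labelled Ucp1-KO. Array weights gave 2738 interactions of genotype with diet in iBAT and 4706 in iWAT, 3614 of genotype with temperature in iWAT, 2630 genes for genotype in iWAT on high fat diet and 5063 for diet in wild-type iWAT. Fits of only the groups compared gave 1442 for diet in Ucp1-KO iBAT, 13 for genotype in iWAT on high fat diet and 373 for the interaction with diet in iWAT.

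With muscle and B cell covariates, genotype gave 5908 genes in iBAT on high fat diet, and in iWAT 6615 at 20 °C, 1164 at 30 °C and 81 on high fat diet, with 72 interactions with diet. Between tissues the covariates gave 5606, 6360 and 6469 genes in wild-type mice at 20 °C, at 30 °C and on high fat diet, and 6472 and 7168 in Ucp1-KO mice at 20 °C and on high fat diet, where the higher shares turned to 58.7% and 58.4%. Without the 15 libraries the counts were 1298 for diet in Ucp1-KO iBAT, 550 for its interaction with genotype, 1001 for genotype in iWAT at 30 °C, 1025 for diet in wild-type iWAT and 47 for the interaction with diet in iWAT. The covariates and the 15 libraries rest on muscle and B cell genes, whose own changes were bound to shrink in these settings. Between tissues the B cell mean nearly stands for the tissue, with group means up to 1.47 in iBAT and from 3.60 in iWAT. Tissue counts and shares with the covariates therefore decide nothing. Of the 423 list tests 28 passed with an estimated correlation, against 208.

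Of 4107 values of named genes under the alternatives, 3980 kept direction and call, 123 lost the call, and Cidea (1.38) and Elovl3 (1.22) gained it with array weights in iWAT on high fat diet. With the covariates 2 muscle genes reversed on high fat diet in iWAT, Ckm in wild-type (0.15) and Myh4 with the label Ucp1-KO (0.091). Both belong to the muscle list whose mean is the covariate, which holds their change near 0, so these reversals decide nothing.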

Other observations

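The comparison of clock genes between tissues, the search for genes with the same direction in all genotype comparisons, the correlation of B and T cell markers, and all repeats with other splits were chosen after the results were seen. In wild-type iWAT 3 of 16 clock genes passed the temperature test, the same adjusted over the list alone, and Arntl, a driver of the clock, was at −0.46 and not called without the 15 libraries. Across the 16 clock genes the temperature changes of iBAT and iWAT went together (r = 0.726, permutation p = 0.0017). Adjusted over the Pearson and Spearman coefficients of this comparison, the permutation p was 0.0034. Without the 2 farthest genes r was 0.669, and over all genes tested in both tissues it was 0.399. The permutations exchanged genes, so their p sets the clock r against 0 and not against the r of all genes. Of the 16 clock genes 12 had the same sign. Clock genes regulate each other, and both tissues came from the same animals per the series design, so neither genes nor tissues are independent replicates.

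Red cell genes passed in 3 of 5 comparisons of genotype or diet in iBAT, and none passed for genotype at 30 °C on control diet or for diet in Ucp1-KO. All 5 erythroid markers were higher in Ucp1-KO than in wild-type iBAT at 20 °C, rose on high fat diet in wild-type iBAT, and were lower in Ucp1-KO than in wild-type iBAT on high fat diet, where 1 of 5 stayed without the 15 libraries (5 and 4 of 5 in the other 2 comparisons). In iWAT labelled Ucp1-KO all 5 fell on high fat diet, and 4 without the 15 libraries. Mest reached 84.9 ± 77.3 RPKM on high fat diet in wild-type iWAT (SD, n = 8) and 84.3 ± 79.0 in iWAT labelled Ucp1-KO, from 5.01 ± 1.49 and 3.67 ± 1.30 on control diet at 30 °C.

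Ucp1, whose direction differed between the tissues, was left out of the search: 5 of 14539 other genes tested in both tissues were called in the same direction in all 6 genotype comparisons. Acsl1, Krt79, Psma1 and Usp38 were higher with Ucp1-KO and Scoc was lower. Of these 5, Acsl1, Usp38 and Scoc lie on the chromosome of Ucp1, at places −199, −6 and 2 from it among the tested genes. Acsl1 was not among the 200 nearest tested genes. Scoc ran from 1.77 to 3.67 RPKM in Ucp1-KO iBAT and from 6.22 to 10.3 RPKM in wild-type iBAT, while in iWAT the ranges overlapped (up to 4.13 with the label Ucp1-KO, from 4.05 in wild type). The B and T cell means of iWAT libraries went together within groups (r = 0.958).

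Each count of genes was set against 100 splits of its libraries, the real split included. For temperature in iBAT only the real split, 1 of 100, gave as many genes (6610 in wild-type and 10866 in Ucp1-KO; highest other 4500 and 7629), so chance was argued against. A share of 1 of 100 is the lowest that 100 splits can give, and it was not adjusted over the 26 comparisons. For genotype in iBAT it was also 1 of 100, with 5601 genes at 20 °C, 9583 at 30 °C and 9458 on high fat diet against 3354, 7740 and 5727. For diet in iBAT, 4890 and 2424 genes in wild-type and Ucp1-KO stood against 1618 and 558, and for the interactions with temperature and diet 7762 and 970 against 125 and 532, each 1 of 100.

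In iWAT chance was argued against, at 1 of 100 splits each, for temperature (3116 genes in wild-type iWAT and 9598 in iWAT labelled Ucp1-KO against 76 and 6792), for genotype at 20 °C and 30 °C (10305 and 3781 against 5970 and 884), for diet (2150 and 3873 against 83 and 1359) and for the interaction with temperature (2110 against 0). For genotype on high fat diet 6 of 100 splits gave as many as the 45 genes, up to 3037, so chance was not excluded. For the interaction with diet 2 of 100 splits gave as many as the 212 genes, up to 3671. That share is below 0.05, but like the others it is not adjusted over the comparisons. The count also moved widely under the alternatives, so chance stays open for it. What the splits that call several times the real number separate was not tested.

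Between tissues the real split alone, 1 of 100, gave as many genes in each comparison. The highest others were 11929, 12246 and 11538 for wild-type mice at 20 °C, at 30 °C and on high fat diet (13082, 13263 and 12823 genes), and 8895, 5803 and 9338 for Ucp1-KO mice (10254, 10142 and 11331 genes). For the differences between tissues in the response to temperature they were 139 against 2738 genes in wild-type and 1418 against 4160 in Ucp1-KO mice.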
